A study of Mus musculus with 20 samples.

How the data were processed

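Liver RNA of 20 gonadectomized C57BL/6J mice was measured on 20 arrays, 1 per animal. The mice came from the FCG (core genotypes) cross, in which the Y chromosome lacks Sry, the testis-determining gene, and an autosome carries Sry as a transgene. Sex chromosomes and gonads were therefore inherited separately, and the labels gave 4 groups of 5 animals: XX gonadal males (XXM), XY gonadal males (XYM), XX gonadal females (XXF) and XY gonadal females (XYF). Gonadal males carried the transgene and gonadal females did not. The animals ate chow with 4% fat, lost their gonads at 8 weeks and were killed at 12 weeks after a fast of 12 h. Replicates were named by animal number, and all numbers differed, so that each array was a separate animal and nothing paired the groups.

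Per the labels' protocols, RNA was isolated on RNeasy spin columns with DNase and labelled by an automated aminoallyl procedure built on the MessageAmp II kit, with the liver in Cy5 and a common liver pool in Cy3. The labels described the pool as liver of 17 chow-fed mice, whereas the design text described equal shares of RNA from each sample. Which is right stayed open, but the pool cancels in every comparison between groups. The scanner, background correction and dye normalization were not given in the sources used here.

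The deposited values were log10 ratios of liver over pool for 23574 probes, as read from the values themselves, because neither labels nor headers gave the log base or the direction. They were limited at a size of 2, where 29 values lay, and 2 values were missing. In base 10, the Y-linked genes Eif2s3y and Kdm5d stood at 1.74 ± 0.33 and 1.68 ± 0.49 times the pool (SD, n = 9 arrays of XY livers without the library labelled XYF 30). In base 2 these ratios were 1.18 and 1.16 and in base e 1.27 and 1.24, against 2 for a pool with equal shares of XX and XY RNA. Base 10 and liver over pool were therefore used, and values were converted to log2. Another base would scale every log2 difference by a common factor and leave limma's p-values as they are.

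The platform annotation listed 13713 of the probes. Of these, 12662 were named through an Entrez ID in the mouse gene table (assembly GRCm38.p6, used for names, chromosomes and gene order only), 4 through an accession, 999 kept the platform's own symbol and 48 named several genes. Another 9861 probes were not listed and stay unnamed here. Probes that named the same gene alone were averaged, which gave 21643 features: 11734 named genes and 9909 single probes. Averages over more than 1 probe made up 1244 features. No value was filtered on intensity, since the values are ratios.

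Comparisons were fitted with limma 3.58.1 in R 4.3.3 on log2 ratios, with a mean for each of the 4 groups and a spread shared by all 20 arrays. Contrasts gave the effect of sex chromosome complement (XX minus XY over both gonadal types), of gonadal type (gonadal males minus gonadal females over both complements), their interaction, and the effect of each factor within each level of the other. Moderated tests (eBayes) were adjusted by Benjamini-Hochberg over all features, with a threshold of 0.05 on the adjusted p. Errors of differences are limma's standard errors (SE). Fisher's exact test compared X-linked with other placed genes.

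Gene lists were fixed before the data were examined: Y chromosome genes; X genes known to escape inactivation; the distal X interval from Tmsb4x to Mid1; male-biased and female-biased liver genes; cholesterol synthesis; fatty acid synthesis; fatty acid oxidation and ketogenesis; gluconeogenesis and fasting response; bile acid synthesis and transport; lipoprotein genes; drug-metabolism genes of the CAR and PXR response; interferon response; acute phase; circadian clock and its outputs; growth hormone and STAT5 targets; cell cycle; heat shock and ER stress; immediate early genes; gonadal and adrenal steroid genes; and markers of pericentral and periportal hepatocytes, Kupffer cells and macrophages, lymphocytes, stellate cells and fibroblasts, sinusoidal endothelium, cholangiocytes, erythroid cells and blood, pancreatic acini and adipocytes. Of 605 list entries, 458 were measured. The 30 lists were tested with camera (limma) at a preset correlation of 0.01 for the effects of sex chromosomes, gonadal type and their interaction, and adjusted by Benjamini-Hochberg over all 90 tests. Camera with an estimated correlation and fry, with its directional and its mixed test, were run beside it.

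Genes were named by a rule that was also fixed before the data were examined: sex-linked label checks and the measured members of the distal X interval whatever their p; per factorial effect, the 12 named genes with the largest log2 difference in each direction among those past the threshold, or the 5 with the smallest p in each direction where none passed; and up to 4 members with the smallest p of each list described. Beyond this rule, and chosen after their values were seen, are named Gm20747 and Impg1, called only without the library labelled XYF 30, all called members of the sex-biased lists with some that did not pass, members of the glucocorticoid list, and genes shown as examples of the gonadal effect within XX or XY mice.

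The procedure was tested on simulated data for 21642 features with the measured spread, 50 of them changed at each fold. At 1.5-fold, limma recovered 78% of the changed features for sex chromosome complement, 82% for gonadal type and 58% for the interaction. At 2-fold it recovered 98%, 100% and 84%. In simulations with no change it called 0 features, and with changes it called 6 to 14 unchanged features per comparison. The simulated noise was independent between features and arrays, which the real arrays are not, so false calls in the real data may differ. The number of arrays limits the precision of every value.

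Alternatives fixed before the data were examined were single probes in place of gene means, arrays centred on their medians, quantile normalization, array weights, robust eBayes, the more variable part of the features alone, a minimum fold change of 1.2, other thresholds, fits of only the groups compared, and leaving out each animal in turn. Added after the data were examined were fits without the 4 arrays whose log2 ratios had an SD above 0.3, fits with a term for animal numbers up to 15 against those above, and fits of each of these number ranges alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.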

Results

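The livers of 20 gonadectomized mice of the FCG (core genotypes) cross were profiled against a common liver pool, with 5 animals in each of the groups XXM, XYM, XXF and XYF. The cross separates the effect of the sex chromosomes (XX against XY) from that of gonadal type, set by the Sry transgene and by the gonads carried until 8 weeks. Every array gave values for nearly all of the 23574 probes. Array medians lay between -0.0107 and 0.0155 on the log10 scale, and the SD of log2 ratios ran from 0.175 to 0.341. It was above 0.3 on 4 arrays, all of gonadal females (XXF 2, XXF 6, XYF 3 and XYF 12). Correlations between arrays over all probes ranged from -0.54 (XXM 38 with XYF 12) to 0.68 (XXM 9 with XYM 5), and 9 of 190 pairs lay below -0.3. All arrays carried the liver in the same dye, so their direction was kept. No pair of arrays was identical.

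The sex-linked genes were examined first, since they report on the labels. Eif2s3y, a Y-linked gene for a subunit of translation factor eIF2, lay between -5.28 and -2.46 log2 units of the pool in the 10 XX livers and between 0.57 and 1.34 in 9 of the 10 livers labelled XY. The remaining one, the library labelled XYF 30, stood at -3.90. Most of its other sex-linked values also lay outside the range of the other XY livers, though Kdm6a (0.06) lay within the ranges of both. Kdm5d, a Y-linked histone demethylase, was at -3.16, against 0.14 to 1.37 in the other 9 XY livers and -3.03 to -1.22 in XX livers. Eif2s3x, the X-linked partner of Eif2s3y, was at 0.51, against -0.67 to 0.04 in the other XY livers and -0.28 to 0.72 in XX livers. The library labelled XYF 30 thus carried no Y-linked signal above that of XX livers. It was kept in its labelled group, and the main results on sex chromosomes are given also without it. Xist, Ddx3y and Uty had also been chosen for this check, but no probe carried these names in the annotation used.

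**Figure D1:**
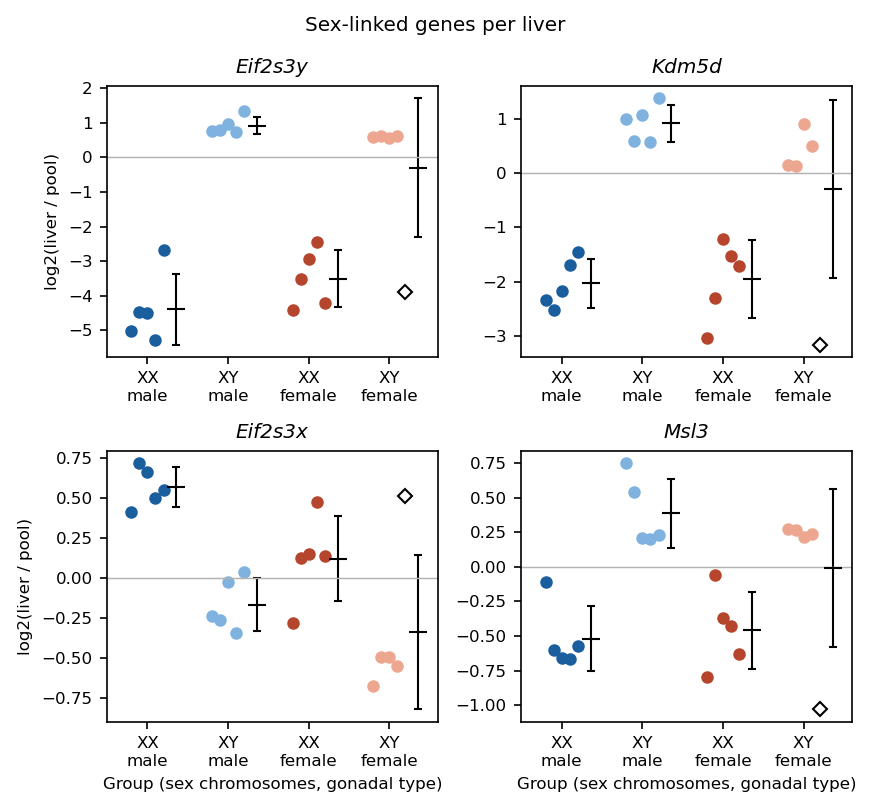
Log2 ratio of liver to pool (vertical axis) of Eif2s3y, Kdm5d, Eif2s3x and Msl3 for each liver by labelled group (horizontal axis); points are animals, the open diamond is the library labelled XYF 30, and bars give the group mean ± SD (n = 5). For Eif2s3y the diamond stands at -3.90 among the XX livers, while the other 9 livers labelled XY lie between 0.57 and 1.34.

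The first comparison asked which liver transcripts depend on the sex chromosomes. Y-linked genes were lower in XX livers: Eif2s3y by 19.2-fold (log2 difference -4.26 ± 0.50 SE, adjusted p = 0.00154), Kdm5d (-2.31 ± 0.39, adjusted p = 0.0444) and Ssty1, a Y-linked spermiogenesis gene family member (-1.02 ± 0.16, adjusted p = 0.0284). XX livers carry no Y chromosome and signal over background was not analysed, so the sizes of the Y-linked differences are not read as changes in expression level. The only autosomal gene past the threshold was Gcsh on chromosome 8, which encodes the H protein of the glycine cleavage system. It was 1.57-fold lower in XX livers (-0.65 ± 0.10, adjusted p = 0.0198). With 2 unnamed probes (-5.23 and 0.30), limma called 6 features, 1 higher and 5 lower in XX. An unadjusted p under 0.05 was reached by 1099 features, close to the share of 0.05 of all 21643 that chance gives. Without the library labelled XYF 30 this number was 1438, above that share. The calls then numbered 13, of which 5 were among the 6. Eif2s3y then differed by -4.71 (26.2-fold, adjusted p = 1.09e-07), Kdm5d by -2.67 and Ssty1 by -1.17. Eif2s3x was then 1.63-fold higher in XX livers (0.70 ± 0.08, adjusted p = 1.88e-04), and Msl3, an X-linked gene of a histone acetylation complex, was 1.75-fold lower (-0.81 ± 0.10, adjusted p = 6.22e-04). Gm20747 of the Y chromosome (-1.41), Gcsh (-0.72) and the autosomal retinal gene Impg1 (-0.46) were also lower. The X chromosome held 2 of the 8 called genes with a known place (odds ratio 8.92, Fisher's exact p = 0.0316), against 0 of 4 with all 20 arrays (odds ratio 0, p = 1). Kdm5d was past the threshold in only 1 of 20 fits that left out an animal, Ssty1 in 5 and Gcsh in 14, whereas Eif2s3y was in all 20. Every fit in which Kdm5d, Ssty1 or Gcsh failed kept the library labelled XYF 30. Without that library their adjusted p by limma was 2.1e-06, 9.8e-07 and 1.88e-04. The count of 6 became 2 without XXM 18, XYM 14, XXF 6, XXF 29, XYF 22 or XYF 24, and 3 without XXM 9, XYM 20, XYM 27, XXF 21, XXF 35, XYF 3 or XYF 12. Without the 4 arrays of wide spread, 0 features passed in limma, although Eif2s3y still differed by -3.81 (adjusted p = 0.266). The XYF arrays left in that fit were XYF 22, XYF 24 and the library labelled XYF 30. The fit therefore does not show that the calls rest on the wide arrays. With a term for animal number Kdm5d did not pass (adjusted p = 0.0569), whereas Eif2s3y, Ssty1 and Gcsh did.

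X-linked genes that escape inactivation in XX cells did not pass as single genes with all 20 arrays. Kdm6a, a histone demethylase, differed by 0.73 (adjusted p = 0.297; 0.81 with adjusted p = 0.0572 without the library labelled XYF 30), Eif2s3x by 0.60 (adjusted p = 0.216), the RNA helicase Ddx3x by 0.14 and Kdm5c by -0.02. Of the 7 measured members of the escape list, 0 passed over all features and 2 higher in XX, Eif2s3x and Kdm6a, passed adjusted over the list alone. The list's camera test gave an adjusted p of 0.0558, and 0.00782 without the library labelled XYF 30 (adjusted p = 0.0997 with an estimated correlation).

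Genes of the distal X interval from Tmsb4x to Mid1 tended in the opposite direction, with lower values in XX livers. The median of the 9 measured members was -0.19 (camera adjusted p = 2.01e-05; adjusted p = 0.0552 with an estimated correlation). None passed over all features with 20 arrays, and 4 lower in XX passed adjusted over the list alone: Msl3 (-0.68), the actin-binding thymosin Tmsb4x (-1.05), Arhgap6 (-0.19) and Hccs (-0.31). Without the library labelled XYF 30 the adjusted p with an estimated correlation was 0.00445 and 1 member, Msl3, passed over all features. The other members were at -0.33 (Tlr7), -0.19 (Mid1), -0.06 (Tlr8), 0.03 (Frmpd4) and 0.02 (Amelx) in that fit. In gonadal females the mean over the 9 genes was -0.16 ± 0.11 in XX and 0.16 ± 0.16 in XY livers (SD, n = 5 and 4; exact permutation p = 0.0159, two-sided). In gonadal males it was -0.30 ± 0.07 and 0.07 ± 0.12 (SD, n = 5 and 5; exact permutation p = 0.00794), and the groups did not overlap in either gonadal type. The 8 nearest measured genes on the centromere side had a median difference of 0.03 over both gonadal types, but went opposite ways: in XX livers their mean was 0.14 higher in gonadal females (exact permutation p = 0.175) and lower in gonadal males (difference -0.11, exact permutation p = 0.103).

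**Figure D2:**
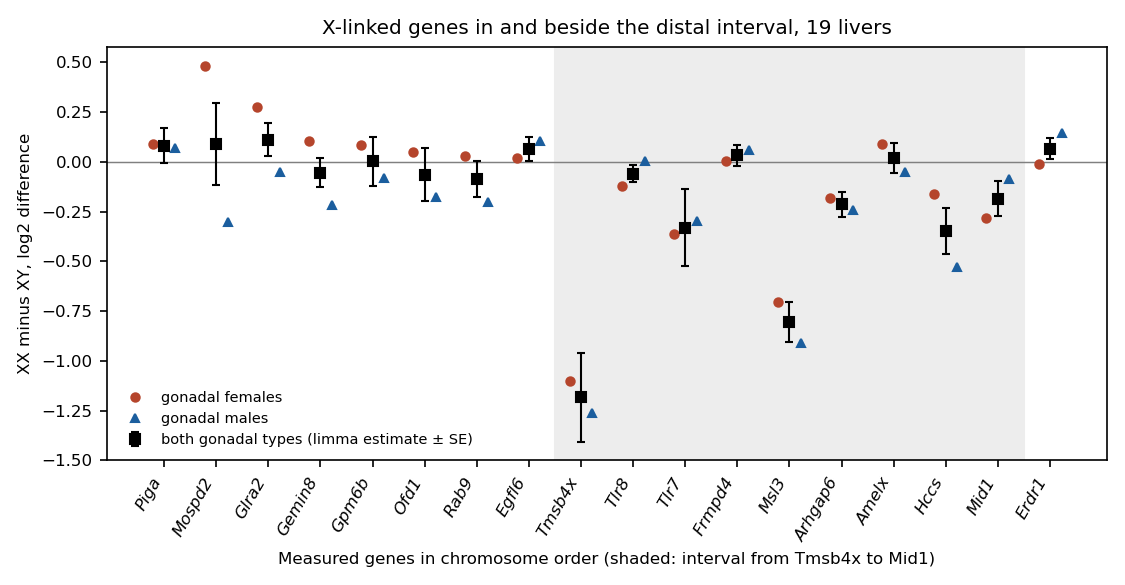
XX minus XY difference in log2 units (vertical axis) of measured X-linked genes in chromosome order (horizontal axis), without the library labelled XYF 30; squares are limma estimates over both gonadal types with their SE, circles gonadal females and triangles gonadal males. Within the shaded interval Tmsb4x and Msl3 lie at -1.18 and -0.81, while the 8 genes to its left have a median of 0.03, with positive values in gonadal females and mostly negative ones in gonadal males.

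Several other lists shifted between XX and XY livers by camera. The Y chromosome list had a median of -0.56 over 6 measured genes, with 3 lower over all features and also when adjusted over the list alone (adjusted p = 4.98e-07; adjusted p = 0.0552 with an estimated correlation). Without the library labelled XYF 30 its median was -0.65, and it passed with the preset correlation (adjusted p = 4.49e-12) and with an estimated one (adjusted p = 2.21e-04). Cholesterol synthesis genes had a median of 0.22 over 16 members (adjusted p = 0.00121), heat shock and ER stress genes 0.12 over 18 (adjusted p = 0.00956) and interferon response genes 0.13 over 28 (adjusted p = 0.0112). Kupffer cell and macrophage markers had a median of -0.17 over 21 members (adjusted p = 0.0242). In each of these last 4 lists 0 members passed, over all features or adjusted over the list alone. With an estimated correlation none of them passed either: the adjusted p was 0.798 for cholesterol synthesis, 0.531 for heat shock and ER stress, and 0.858 for the interferon and macrophage lists. Without the library labelled XYF 30 the adjusted p was 0.00782 for cholesterol synthesis (median 0.19), 0.0203 for heat shock and ER stress (0.12), 0.0116 for interferon response (0.16) and 0.0153 for macrophage markers (-0.20), and with an estimated correlation none of these 4 passed (0.746, 0.628, 0.794 and 0.828). Without the 4 arrays of wide spread the adjusted p was 0.393 for cholesterol synthesis, 0.349 for interferon response and 0.221 for macrophage markers, and 0.00363 for heat shock and ER stress. With a term for animal number the macrophage list did not pass (adjusted p = 0.0733). Leaving out 1 animal lost the cholesterol call (XXF 2 or XXF 6), the heat shock call (XYF 24), the interferon call (XYM 20, XXF 6, XYF 3 or XYF 24) and the macrophage call (XXM 18, XYM 14, XXF 2, XXF 29, XXF 35 or XYF 12). The cholesterol median was 0.0804 without XXF 6 and 0.140 without XXF 2, and the interferon median 0.00476 without XXF 6, 0.202 without XXF 2 and 0.204 without XYF 12. The macrophage median was -0.0889 without XYM 14 and -0.0161 without XYF 12.

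Within gonadal males alone, limma called 1 feature between XX and XY livers, Eif2s3y (-5.32 ± 0.71, adjusted p = 0.00972), with 451 at an unadjusted p under 0.05, fewer than chance gives. Within gonadal females it called 0, with 1317 at an unadjusted p under 0.05. Without the library labelled XYF 30 each comparison called 8 features. Eif2s3y, Kdm5d, Gm20747, Ssty1, Gcsh and Eif2s3x were among the 8 in both. In gonadal males the count was 0 without XXM 9, XXM 32 or XYM 27 and 2 without XXM 38 or XYF 12. Across all features, which are not independent replicates, the sex chromosome effects in gonadal females and males correlated with Pearson's r = 0.25 (jackknife SE 0.253 over arrays) and Spearman's rho = 0.13, and 53.7% had the same sign. These effects share no array. The r was 0.0904 without XYF 12, 0.157 without XYM 20 and 0.161 without XYF 3, and 0.35 without the library labelled XYF 30, so that an agreement over all features was not shown.

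The second comparison asked which transcripts differed between gonadal males and gonadal females 4 weeks after the gonads were removed. Sulfotransferases that conjugate steroids and bile acids had the largest differences: C730007P19Rik, which the mouse gene table lists as an older name of Sult2a2, was 18.1-fold lower in gonadal males (-4.18 ± 0.28, adjusted p = 1.82e-07) and Sult2a1 was 12.9-fold lower (-3.69 ± 0.26, adjusted p = 2.44e-07). Sult2a1 stood at -2.84 ± 0.66 in gonadal males and 0.84 ± 0.56 in gonadal females (log2 ratio to pool, SD, n = 10 each), with no overlap. These paralogs are similar in sequence, and whether the probes separate them was not tested. Sult3a1 (-1.96 ± 0.19), the plasma protein gene A1bg (-2.44 ± 0.39) and the peroxisomal hydroxyacid oxidase Hao2 (-1.47) were also lower in males. Of the genes higher in gonadal males, the cytochrome P450 Cyp2d9 had the largest difference (3.55-fold; 1.83 ± 0.20, adjusted p = 4.47e-05). It was followed by Lpin1, a phosphatidate phosphatase of triglyceride synthesis (1.67 ± 0.22, adjusted p = 4.97e-04), Nat8 (1.59) and the glucocorticoid receptor co-chaperone Fkbp5 (1.21). Omd (1.12), SLC41A3 (1.10, the platform's own symbol), Ptgfr (1.07), Fmo2 (1.03), St3gal5 (0.90), the NADPH oxidase Nox4 (0.85), the insulin signalling adaptor Irs2 (0.84) and Chrdl2 (0.83) completed the 12 named.

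The other named genes that were lower in gonadal males were the interferon-induced chemokine Cxcl9 (-2.10), the guanylate-binding protein Gbp2b (-1.94), the T cell receptor segment Trav9d-3 (-1.81), the ubiquitin-like Ubd (-1.75), the interleukin receptor chain Il2rb (-1.70), the interferon-induced GTPase Tgtp1 (-1.53) and the melanin synthesis enzyme Dct (-1.94). In all, limma called 809 features, 316 higher and 493 lower in gonadal males, with a median size of 0.39 log2 units. Of these, 51 differed by at least 2-fold, and 3842 features had an unadjusted p under 0.05. Without the library labelled XYF 30 the count was 1129, of which 758 were among the 809. Without the 4 arrays of wide spread it was 832, of which only 499 were among the 809. It fell to 393 without XYM 19, 404 without XXM 31, 481 without XXM 18, 493 without XXF 2 and 532 without XYM 27. Irs2, SLC41A3 and Ptgfr did not pass without the 4 arrays of wide spread (adjusted p = 0.126, 0.0655 and 0.0567), and Hao2 failed in 13 and Irs2 in 9 of 20 fits that left out an animal, SLC41A3 in 3 and Tgtp1 in 1. Neither of the 2 probes of Irs2 passed alone (adjusted p = 0.0669 and 0.292).

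**Figure D3:**
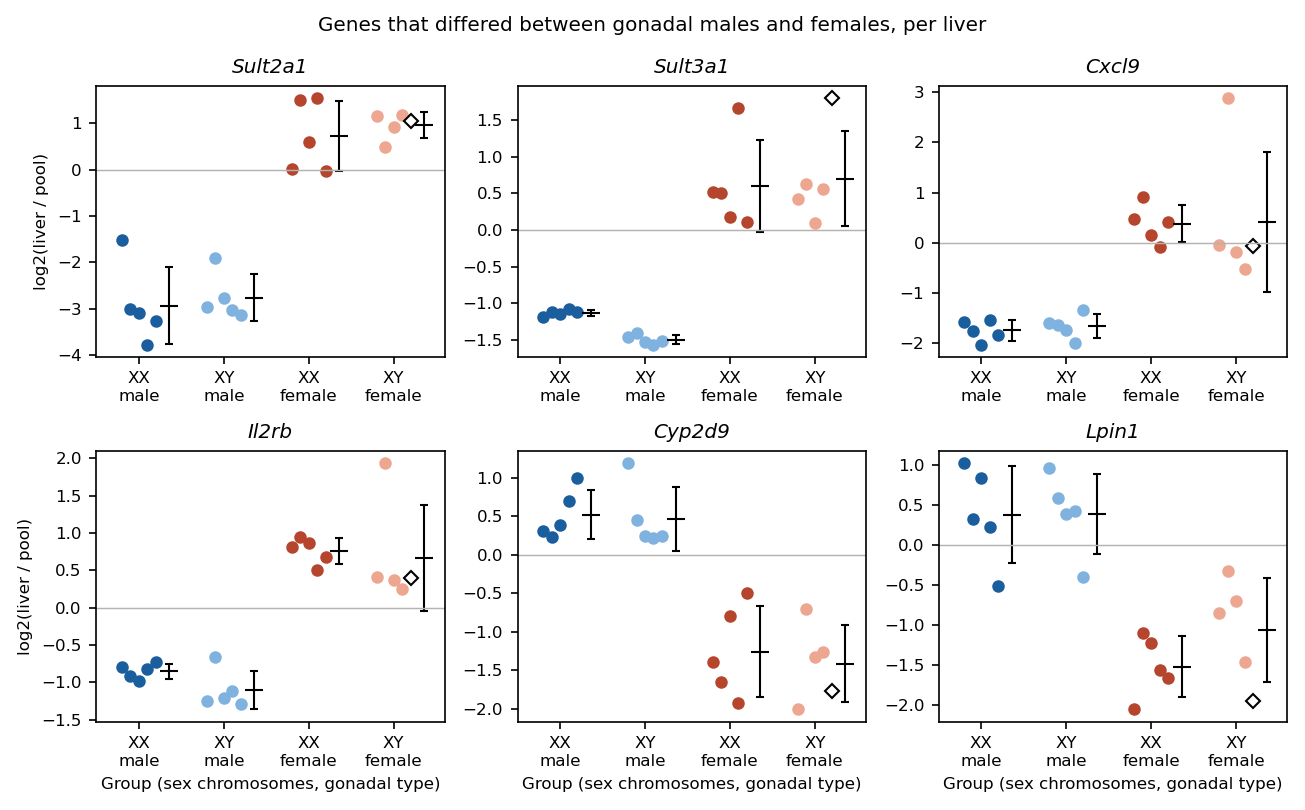
Log2 ratio of liver to pool (vertical axis) of 6 genes for each liver by labelled group (horizontal axis); points are animals, the open diamond is the library labelled XYF 30, and bars give the group mean ± SD (n = 5). Sult2a1 lies at -2.84 ± 0.66 in gonadal males and 0.84 ± 0.56 in gonadal females, and Cyp2d9 runs the other way.

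Genes known for a sex bias in intact liver did not move in a common direction by camera, but fry's mixed test, which counts changes in either direction, passed for female-biased (adjusted p = 1.05e-15) and male-biased genes (adjusted p = 1.93e-07). The mixed test was not particular to these lists. It also passed for others, such as bile acid and fatty acid synthesis (both adjusted p = 2.67e-04) and cell cycle genes (adjusted p = 0.00107). Of 28 measured female-biased genes, 5 were lower in gonadal males (Sult2a1, Sult3a1, A1bg, Hao2 and Cyp2b13 at -0.46) and 2 were higher (Fmo2 and the transcription factor Cux2 at 0.72), with 7 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.101). Some other members lay near 0, such as the cytochromes Cyp3a41a at -0.05, Cyp3a16 at -0.06 and Cyp2b9 at -0.09, which did not pass. Others lay further from 0 in either direction and did not pass either, such as Cyp39a1 (0.76), Acot3 (0.57), Slc22a27 (-0.52) and Cd36 (-0.46). Of 14 measured male-biased genes, Cyp2d9 was the only 1 called, with 2 higher and 1 lower adjusted over the list alone, and the list had a median of 0.01 (adjusted p = 0.989). Cyp7b1 (0.47, adjusted p = 0.0593 by limma), Nudt7 (-0.39), Hsd3b5 (-0.17), Slco1a1 (-0.21), Cyp4a12a (0.08) and Elovl3 (0.17) did not pass.

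Metabolic lists shifted modestly. Genes of gluconeogenesis and fasting response were higher in gonadal males, with a median of 0.14 over 17 members (camera adjusted p = 0.00956). The adjusted p was 0.327 by camera with an estimated correlation and 0.0136 by fry's directional test. Adjusted over the list alone 6 members rose, and over all features 4 did: the glucose-6-phosphate transporter Slc37a4 (0.44), Irs2 (0.84), the aspartate aminotransferase Got1 (0.68) and the urea cycle enzyme Asl (0.41). The call of Irs2 was lost in 9 of 20 fits that left out an animal, and neither of its probes passed alone. Fatty acid oxidation and ketogenesis genes had a median of 0.22 over 22 members, with 0 called over all features or adjusted over the list alone (adjusted p = 0.0336; adjusted p = 0.858 with an estimated correlation). The list's means were -1.21 on XXF 6, -0.78 on XYF 3 and -0.75 on XXF 2, against -0.12 to 0.23 on the other 17 arrays, and XXF 6 and XXF 2 also had the highest means of cholesterol synthesis genes (1.29 and 0.67). The fatty acid oxidation median was -0.06 without the 4 arrays of wide spread and 0.143 without XXF 6, and the call was lost without XXM 18, XXM 38, XYM 5, XYM 14, XXF 2, XXF 6 or XYF 3. Pericentral hepatocyte markers had a median of -0.13 over 12 members (adjusted p = 0.0131; adjusted p = 0.216 with an estimated correlation), with 2 lower over all features, Lect2 (-0.75) and the ammonium transporter Rhbg (-0.67), and 3 adjusted over the list alone.

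Lists of macrophage, lymphocyte, interferon, stellate cell and erythroid genes were lower in gonadal males by camera with the preset correlation, and none of them passed with an estimated one. By fry's directional test the lymphocyte (adjusted p = 0.00248) and stellate lists (0.00900) passed. The macrophage (0.0536), erythroid (0.137) and interferon lists (0.289) did not. The macrophage list had an estimated correlation of 0.70, against the preset 0.01. Of 21 Kupffer cell and macrophage markers, 8 fell over all features and 16 adjusted over the list alone, with a median of -0.66 (camera adjusted p = 9.00e-13; adjusted p = 0.352 with an estimated correlation). Examples were the complement gene C1qb (-0.63), the Fc receptor Fcgr1 (-1.09), the Kupffer cell lectin Clec4f (-0.82) and the growth factor receptor Csf1r (-0.97). Of 16 lymphocyte markers, 8 fell over all features and adjusted over the list alone, among them Il2rb, Cd2 (-1.45), Cd3g (-1.11) and Ptprcap (-0.85) (median -0.14, adjusted p = 7.22e-08; adjusted p = 0.218 with an estimated correlation). Of 28 interferon response genes, 5 fell over all features and 7 adjusted over the list alone, including Cxcl9, Cxcl10 (-0.999) and the immunoproteasome subunits Psmb9 (-0.79) and Psmb8 (-0.77) (median -0.23, adjusted p = 5.06e-06; adjusted p = 0.613 with an estimated correlation). Without XXF 6 the interferon median was -0.0846. Of 15 stellate cell and fibroblast markers, 5 fell over all features and 7 adjusted over the list alone, with Col1a1 at -0.87, Col14a1 at -0.46, Pdgfrb at -0.39 and Colec11 at -0.24 (median -0.16, adjusted p = 1.55e-06; adjusted p = 0.216 with an estimated correlation). Erythroid and blood markers had a median of -0.40 over 15 members (adjusted p = 8.24e-05; adjusted p = 0.3999 with an estimated correlation), with 1 called over all features, the globin gene Hba-a1 (-0.56), and 5 adjusted over the list alone.

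Sinusoidal endothelial markers, of which 0 of 14 were called over all features or adjusted over the list alone, had a median of -0.05 (camera adjusted p = 0.0845). Cholangiocyte markers had a median of -0.09 over 9 members, with the mucin Muc1 (-0.60) called over all features and alone (adjusted p = 0.0419; adjusted p = 0.218 with an estimated correlation; adjusted p = 0.106 without the library labelled XYF 30; adjusted p = 0.0569 with a term for animal number). That call was also lost without XXM 32, XXM 38, XYM 20, XXF 2 (median -0.0472), XXF 6 or XYF 12. Beside these lists stood the library labelled XYF 12, on which the macrophage markers averaged 1.51, against at most 0.00 in the other livers labelled XYF, and the erythroid markers 1.42. Without XYF 12 the macrophage median was -0.52. It was -0.66 within the 13 animals numbered above 15 and -0.81 within the 7 numbered up to 15.

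**Figure D4:**
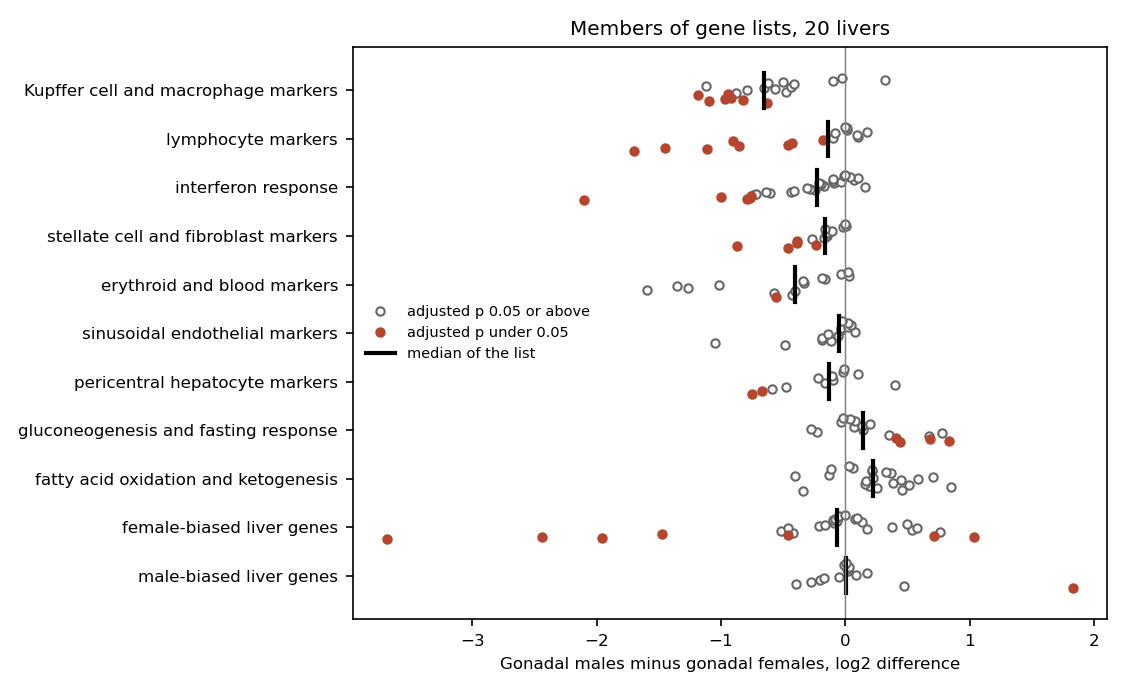
Gonadal male minus gonadal female difference in log2 units (horizontal axis) of each measured member of 11 gene lists (vertical axis); filled points passed an adjusted p of 0.05 over all features, open points did not, and vertical bars are list medians. Most macrophage markers lie to the left of 0, with a median of -0.66, while endothelial markers have a median of -0.05.

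The gonadal difference was then examined within each sex chromosome complement. In XX mice limma called 144 features, 44 higher and 100 lower in gonadal males, and in XY mice 34, 9 higher and 25 lower. Of these, 24 were called in both, all in the same direction, against 0.226 for independent lists of these sizes. The comparisons share no array but share limma's estimate of each feature's spread. The lists are therefore not independent, and 0.226 is too low a bar. C730007P19Rik (-4.14 in XX and -4.22 in XY), Sult2a1 (-3.65 and -3.72), Sult3a1 (-1.72 and -2.19), Il2rb (-1.62 and -1.78), Cyp2d9 (1.78 and 1.88) and Nox4 (0.70 and 1.001) passed in both. Lpin1 (1.89 and 1.45), Cxcl9 (-2.12 and -2.08) and A1bg (-2.64 and -2.24) passed in XX mice, and Nat8 (1.36 and 1.82) in XY mice. The counts 144 and 34 became 170 and 23 without the library labelled XYF 30, and 461 and 51 without XYF 12. In XX mice the count fell to 36 without XXM 31, 48 without XXF 2, 54 without XXM 18, 63 without XXM 38, 75 without XXF 35, 80 without XXM 9 and 86 without XXM 32. In XY mice it fell to 11 without XYM 19, 12 without XYM 5, 17 without XYM 27 or XYF 3, and 21 without XYM 14. That a gene passed in one complement and not in the other does not show a difference between them, which the interaction tests.

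The interaction asked whether the sex chromosome effect depended on gonadal type. Limma called 0 features, with 563 at an unadjusted p under 0.05, fewer than chance gives. The smallest adjusted p was 0.9995, and 0 features were called under every alternative run. The genes with the smallest p did not pass: Cpne6 (0.27), Ankhd1 (0.69), Slc37a4 (0.55), Tcl1b5 (0.34) and Ctla4 (0.28) had positive values, and AI428479 (-0.84), Lrp2_29216 (-0.38, the platform's own symbol), St3gal3 (-0.36), Foxo4 (-0.31) and Cyp2r1 (-0.77) negative ones. The 2 probes of Ankhd1 differed, at -0.06 and 1.43. By camera 3 lists passed, each with 0 members called over all features or adjusted over the list alone. Cholesterol synthesis genes were higher in XX than XY livers in gonadal females (median 0.43) and not in gonadal males (0.01), with an interaction median of -0.35 (adjusted p = 0.00315; adjusted p = 0.816 with an estimated correlation). Interferon response genes had medians of 0.22 and 0.00, and an interaction median of -0.21 (adjusted p = 0.0154; adjusted p = 0.858 with an estimated correlation). Gluconeogenesis genes had medians of -0.14 and 0.08, and an interaction median of 0.21 (adjusted p = 0.0256; adjusted p = 0.352 with an estimated correlation). All 3 passed without the library labelled XYF 30 with the preset correlation (adjusted p = 0.00782, 0.00799 and 0.0153 in this order) and none with an estimated one (0.746, 0.791 and 0.388). Without the 4 arrays of wide spread none of the 3 passed (adjusted p = 0.988, 0.828 and 0.0894 in this order), and the cholesterol median was 0.03. The cholesterol call was lost without XXF 2 or XXF 6, and its median was -0.116 without XXF 6, -0.215 without XYM 5 and -0.230 without XYF 22. The interferon call was lost without XXM 31, XYM 27, XXF 6, XYF 3 or XYF 24, and its median was 0.06 without XXF 6, -0.127 without XYM 27 and -0.355 without XXF 2. The gluconeogenesis call was lost without XXM 9, XYM 19, XYM 20, XXF 2, XXF 35, XYF 12 or XYF 24, with a median of 0.125 without XYF 24.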

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

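The explanations weighed here were prompted by results already seen. The tests of the library labelled XYF 30, of a further active copy of the distal X interval, of its neighbours within each gonadal type and of hepatocyte share were chosen only after the result was seen, as were the fits without the 4 arrays of wide spread or with animal number. Of 256 groups of 5 livers screened over 51 genes and 13 lists, 37 (14.5%) had a liver far from the other 4, where chance gives about 1 in 20. These livers were concentrated on a few arrays.

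The library labelled XYF 30 lay far from the other livers of its group for Eif2s3y (-3.90), Kdm5d (-3.16), Ssty1 (-0.86), Msl3 (-1.03), Eif2s3x (0.51) and the mean of the Y chromosome list (-1.35). A turned ratio sign is argued against, since Eif2s3y would then stand at 3.905, above the 1.34 of the highest other XY liver; so is a swap with an XX array of this set, since 0 of 10 had Y-linked signal. Loss of the Y chromosome with a single X is argued against by Eif2s3x at 0.51, above the 0.04 of the highest other XY liver. For the liver of an XX animal under an XY label, a bound that all 6 sex-linked genes lie within the XX range was missed, since 3 did; Kdm5d, Gm20747 and Msl3 lay below that range, on the side away from XY. With these 3, a bound against an XX animal was met: at least 2 of the 6 genes outside the XX range or inside that of the other XY livers. Neither bound decides, since 1 further array can leave a range of 10 by chance. None of the 6 genes lay in the range of the other XY livers, though Kdm6a, not among the 6, lay in both ranges. The liver may be of an XX animal from outside the 20 or under a wrong label, which stays open.

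Genes of the distal X interval were lower in XX livers, against the direction of X copy number. More leukocytes in XY livers are argued against for Msl3, whose difference was -0.78 with the macrophage mean as a covariate and -0.81 without it; Tlr7, a gene of immune cells, went from -0.33 to -0.16. A like shift of neighbouring X-linked genes was not seen in gonadal females, where the 8 nearest genes on the centromere side had a median of 0.0878. In gonadal males it was -0.129. By exact permutation over animals the mean of these genes differed in neither (p = 0.175 and 0.103). The median over both, 0.0329, hides these directions and decides nothing. These 8 genes cannot stand for X-linked genes at large, whose shift was not tested and stays open. A further active copy of the interval in XY livers, for instance on the Y chromosome of this cross, would give differences in both gonadal types. These were seen (the larger exact permutation p was 0.0159). Such a copy remains a hypothesis on the data that raised it, beside a wider shift along the X. Neither the position nor the copy number of these genes can be read from expression, and Frmpd4 and Amelx stood at 0.03 and 0.02.

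The macrophage, lymphocyte and interferon lists were higher in gonadal females by camera with the preset correlation. A lower share of hepatocytes would raise all other cell types. An equal rise is argued against for the macrophage list, whose mean minus the endothelial mean was lower in gonadal males. The difference was -0.50 (two-sided exact permutation over animals, p = 0.00869, at most 0.0170 without 1 animal, XYM 20). The stellate, erythroid, cholangiocyte and endothelial lists also had negative medians (-0.16, -0.40, -0.09 and -0.05). Weak probes could not be told from strong ones, so equal sizes cannot be relied on. A lower share of hepatocytes as part of the shift stays open. The 4 arrays of wide spread were all the gonadal females numbered up to 15, so spread and animal number are not separate explanations. The macrophage median was -0.55 without these arrays and -0.63 with a term for animal number, against -0.66. That term assumes the same shift in both gonadal types. Within the 13 animals above 15, none of them wide, the median was also -0.66, which argues against spread or number as the whole source. More or more active immune cells in gonadal females, set by the transgene or by hormones before gonadectomy, may account for the shift. This is a hypothesis that expression in whole liver cannot separate further. Each list call was lost with an estimated correlation.

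On XYF 12, 10 values lay far above the other livers of the group: Cxcl9 (2.88), Ubd (3.15), Tgtp1 (2.58), Gbp2b (2.30), Il2rb (1.94), Trav9d-3 (1.93), Tlr7 (1.10), and the means of macrophage (1.51), erythroid (1.42) and lymphocyte markers (0.70). On XXF 6 the mean of interferon genes (1.195), Tgtp1 (1.87), Gbp2b (1.41) and Tlr7 (0.45) lay above the group. On XYM 14, Tmsb4x (0.52), the macrophage mean (0.37), Sult2a1 (-1.90) and Il2rb (-0.67) lay above the group. On XYM 27, Dct (-1.92), St3gal5 (-0.10) and Slc37a4 (-0.37) lay below it. Among XXM livers, Tmsb4x was low on animal 31 (-1.68). Frmpd4 (0.17) and the Y chromosome list (-0.74) were high on animal 38, and Msl3 (-0.11) was high and SLC41A3 (-0.53) low on animal 9. Cyp2r1 (-0.0235) and lymphocyte markers (-0.15) were high on animal 32. Single values stood out for Cyp2d9 on XYM 5 (1.19), Tcl1b5 on XYM 20 (0.0910) and Sult3a1 on XXF 29 (1.66).

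The sex chromosome effect on 3 lists differed between gonadal types by the camera test of the interaction: cholesterol synthesis (median -0.35), interferon response (-0.21) and gluconeogenesis and fasting response (0.21). None held with an estimated correlation, with adjusted p of 0.816, 0.858 and 0.352.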

How the results depend on the processing

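The fits without the 4 arrays of wide spread, with a term for animal number, and within a range of animal numbers were chosen after the data were examined; the others were planned. For values named singly, 1583 results under an alternative kept direction and side of the threshold, 128 fell short of it, 7 newly passed, 3 moved and 9 reversed. The interaction and XX minus XY in gonadal females stayed at 0 calls by limma in all alternatives that kept every animal of the set or left out those of wide spread. The cause of the changes below was not tested, except where fewer arrays or another threshold bring them about by construction.

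Array weights gave 12 calls for sex chromosome complement (6), 1679 for gonadal type (809), 7 for XX minus XY in males (1), 571 for gonadal type in XX mice (144), 56 in XY mice (34) and 2 autosomal calls (1). A minimum fold of 1.2 gave 2, 32, 10 in XX mice and 9 in XY mice. An adjusted p under 0.01 gave 1, 193, 30 and 11 for the same comparisons, and an adjusted p under 0.1 gave 11, 1485 and, for gonadal males minus females in XX mice, 285, with 2 in XX minus XY in males. Quantile normalization gave 2 in XX minus XY in males, 405 in XX mice and 56 in XY mice; the more variable features alone gave 3 in XX minus XY in males. Fits of only the 2 groups compared gave 10 in XX minus XY in males, 387 for gonadal males minus females in XX mice and 4 in XY mice. Without the wide arrays, and with the library labelled XYF 30 kept, sex chromosome complement had 0 calls and XX minus XY in males 2. Gonadal type then had 832 calls, of which 499 were among the 809, with 274 in XX and 52 in XY mice. In that fit 11 lists passed (18). The number term gave 56 in XY mice. The 13 animals above 15, with the library labelled XYF 30 among them, gave 0 calls for sex chromosomes. The 7 up to 15 left 1 animal in XXM, so their counts are not given. Camera with an estimated correlation called 0 lists and fry's directional test 7. For sex chromosome complement these were the distal X (fry adjusted p = 0.00907) and Y chromosome lists (0.00248). For gonadal type they were the gluconeogenesis (0.0136), pericentral (0.00900), cholangiocyte (0.00995), lymphocyte (0.00248) and stellate lists (0.00900).

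Leaving out 1 animal gave 2 to 13 calls for sex chromosome complement. The count was 2 without XXM 18, XYM 14, XXF 6, XXF 29, XYF 22 or XYF 24, 3 without XXM 9, XYM 20, XYM 27, XXF 21, XXF 35, XYF 3 or XYF 12, and 13 without XYF 30. Gonadal type ranged from 393 (XYM 19) to 1129 (XYF 30), with 404 (XXM 31), 481 (XXM 18), 493 (XXF 2) and 532 (XYM 27). The interaction ranged from 0 to 0. XX minus XY in females ranged from 0 to 8 (XYF 30), and in males from 0 (XXM 9, XXM 32, XYM 27) to 8 (XYF 30), with 2 without XXM 38 or XYF 12. Gonadal type in XX mice ranged from 36 (XXM 31) to 461 (XYF 12), with 48 (XXF 2), 54 (XXM 18), 63 (XXM 38), 75 (XXF 35), 80 (XXM 9) and 86 (XXM 32). In XY mice it ranged from 11 (XYM 19) to 51 (XYF 12), with 12 (XYM 5), 17 (XYM 27 or XYF 3) and 21 (XYM 14). Autosomal calls ranged from 0 to 2, the agreement r from 0.0904 (XYF 12) to 0.351 (XYF 30), and lists from 12 (XXF 2) to 27 (XXF 21).

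Without the 4 arrays of wide spread, the median of fatty acid oxidation and ketogenesis, gonadal type, reversed to -0.0579, and the median of cholesterol synthesis, interaction of sex chromosomes and gonadal type, to 0.0306. The interferon response interaction was 0.0587 without XXF 6 and moved to -0.355 without XXF 2. Kdm5c became 0.0056 without XXM 9 and 0.0044 without XXF 29, and moved to -0.0343 without XYF 12. Amelx moved to 0.0629 without XXF 29 and became -0.0073 without the wide arrays, -0.0031 without XXF 6 and -0.0124 without XXF 21. The first probe of Ankhd1 stood at -0.0612. No paired analysis was possible because every animal number differs. Signal over background was not analysed here, since the values are ratios, so that weak probes could not be told from strong ones.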

Other observations

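The tests of animal number, of the chromosomes of called genes and of glucocorticoid-induced genes were chosen after the result was seen, the last with a list written before it was tested; the splits were planned. Some lists that did not pass camera for gonadal type held single genes that passed over all features. In bile acid synthesis and transport, Klb, the co-receptor for fibroblast growth factors that regulate bile acids, was higher in gonadal males (0.51, 1 of 21 members; 2 adjusted over the list alone). Among lipoprotein genes, Mttp, the triglyceride transfer protein, was higher (0.47, 1 of 17; 1 higher and 2 lower adjusted over the list alone). Among genes of fatty acid synthesis Lpin1 was the only member called, of 19 (camera adjusted p = 0.330). In drug metabolism the retinal dehydrogenase Aldh1a1 was lower (-0.57, 1 of 18; 2 adjusted over the list alone), in cholesterol synthesis the squalene synthase Fdft1 (-0.77, 1 of 16; 2 alone), and among steroid genes Hsd17b2, which inactivates sex steroids (-0.40, 1 of 9; 1 alone). Cux2 was the only one of 11 growth hormone and STAT5 targets called. Of 22 cell cycle genes, the ribonucleotide reductase subunit Rrm2 was higher (0.41) and Cdc20 lower (-0.16), with 2 higher and 3 lower adjusted over the list alone. The distal X gene Tmsb4x was lower in gonadal males too (-0.89, adjusted p = 0.0486 by limma).

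Other lists had no member past the threshold over all features for gonadal type. Acute phase genes had a median of -0.01 over 19 members (camera adjusted p = 0.286), although Saa1, Saa2 and Saa3 stood at -1.14, -1.42 and -1.12. Clock genes had a median of 0.01 over 17 members (adjusted p = 0.843), immediate early genes 0.01 over 15 (adjusted p = 0.876), and heat shock and ER stress genes 0.06 over 18 (adjusted p = 0.989; 1 higher and 2 lower adjusted over the list alone). Periportal markers had a median of -0.02 over 9 (adjusted p = 0.989; 1 higher and 1 lower alone) and adipocyte markers 0.02 over 8 (adjusted p = 0.961; 1 higher and 1 lower alone). Pancreatic acinar markers, which would point to tissue beside the liver, had a median of -0.07 over 6 (adjusted p = 0.399).

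Fkbp5 and Lpin1, both known to respond to glucocorticoids, were among the genes higher in gonadal males, and a hypothesis was that glucocorticoid-induced genes were higher at large. A list of 19 other such genes was written before the test, and 13 were measured. Their median was -0.03, 0 were called by limma and camera gave p = 0.577 (p = 0.713 with an estimated correlation). Tat (0.35) and Cdkn1a (0.60) were positive and Tsc22d3 (-0.28) and Sgk1 (-0.20) negative, each short of the threshold. The median lay below 0, the bound set against the hypothesis, but by less than its spread, so that the question stayed open.

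Arrays of animals with close numbers resembled each other. After group means were removed, the correlation between arrays fell with the difference of animal numbers (Spearman's rho = -0.54 over 190 pairs; one-sided permutation p = 1.00e-04, the smallest that 10000 permutations can give). The median correlation was 0.154 for pairs numbered up to 15, -0.181 for mixed pairs and 0.0525 for pairs above 15. Among the 13 arrays above 15 alone the permutation p was 0.0561 (rho = -0.15). A shared day, cage or litter may lie behind this, as a hypothesis seen in the data first, since the labels give no batch. Animals up to 15 numbered 1 in XXM and 2 in each other group.

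If the transgene's insertion affected its neighbours, genes called for gonadal type could cluster on a chromosome. Over the 19 autosomes the smallest adjusted p was 0.375 (one-sided Fisher's exact test), for chromosome 17 with 33 of 516 genes called, or 6.40%. The insertion site was not given in the sources used here, and a single short region would escape this test, so that linkage stayed open.

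Each count of calls was set against 100 splits of the arrays into groups of the same sizes, the real split included. The real split alone gave as many calls in 1 of 100 for sex chromosome complement (6; highest other 4), gonadal type (809; highest other 110), and gonadal type in XX mice (144; highest other 1) and in XY mice (34; highest other 19). For gonadal type, over both complements and in XX mice, the splits argue against chance but do not exclude it, since 100 splits cannot reach below 1 in 100. The counts without any 1 animal (393 and 36 at the lowest) stayed above the highest other. That highest other came from splits of all 20 arrays, not from splits without the same animal. For sex chromosome complement the count was 2 or 3, under the highest other, without XXM 9, XXM 18, XYM 14, XYM 20, XYM 27, XXF 6, XXF 21, XXF 29, XXF 35, XYF 3, XYF 12, XYF 22 or XYF 24. In XY mice it was 11 without XYM 19, 12 without XYM 5 and 17 without XYM 27 or XYF 3, also under the highest other. For these comparisons the splits are therefore not taken to exclude chance. The fits with 2 or 3 calls for sex chromosome complement all kept the library labelled XYF 30, without which the count was 13. For Eif2s3y and Kdm5d themselves, chance is argued against by their values. Eif2s3y lay at -5.28 to -2.46 in the 10 XX livers and 0.57 to 1.34 in the other 9 XY livers. Kdm5d lay at -3.03 to -1.22 and 0.14 to 1.37. For XX minus XY in gonadal males, 3 of 100 splits gave as many as the real 1 (highest other 1). Other splits reached this count, and the call was lost without XXM 9, XXM 32 or XYM 27. The splits are thus not taken to exclude chance for this count either. The splits do not hold animal number fixed. For the interaction (0; highest other 1) and for XX minus XY in gonadal females (0; highest other 914), 100 of 100 splits gave as many, as they must with a real count of 0, so that these splits say nothing about chance. The split with 914 calls set XXF 6, 21, 29 and 35 with XYF 12 against XXF 2 with XYF 3, 22, 24 and 30, which is the real split with XXF 2 and XYF 12 exchanged, and points to a structure among the gonadal female arrays. XXF 2 and XYF 12 are among the 4 arrays of wide spread.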
